A study of Mus musculus with 8 samples.

How the data were processed

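The series holds 8 Illumina MouseRef-8 v2.0 arrays of total RNA from CD4 T cells sorted from mesenteric lymph nodes, 1 array per combination of genotype, sorted population and stimulation, with no repeat of any combination. Groups were read from the labels and written down before the data were examined. Per the labels' protocols the RNA was extracted with Trizol and labelled with biotin, and the stimulated set received antibodies against CD3 and CD28 for 30 min.

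The deposited non-normalized table gives for each of 25697 probes and each array a mean bead intensity on a linear scale, with its standard error, the number of beads and a detection p-value, per the file headers. The detection p-value was made by the authors' scanner software from negative control probes, and its values fall on whole steps of a fraction with 800 parts. The deposited value table holds log2 values of 14533 probes, which are those with a detection p under 0.05 on at least 1 array. Each array of it correlates with the neqc values computed here at 0.999998 or above, with differences of at most 0.0539 log2, so that it is on the log2 scale, quantile normalized and not centred. The labels name limma for the authors' processing, and its version and the scanner software are not given in the sources used here. All array columns of values were used.

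From the intensities, log2 values were computed with the neqc method of limma 3.58.1 in R 4.3.3: normexp background correction from the detection p-values, an offset of 16 and quantile normalization. Probes with a detection p under 0.01 on at least 2 of 8 arrays were tested, 11047 probes of 8104 genes. Linear models were fitted with lmFit and eBayes, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. Matched combinations were taken as pairs, which entered as blocks. The pairing comes from the factorial labels, not from shared animals, and the differences of pairs correlated across probes at 0.0256 to 0.419 for genotype, 0.33 to 0.72 for stimulation and 0.387 to 0.814 for population. Comparisons over all pairs left 3 residual degrees of freedom. Comparisons within a population and differences between them came from a model with separate effects per population (or per stimulation state), with 2 residual degrees of freedom and an error estimate shared by the populations.

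Per array, 9208 to 10477 probes were detected at a detection p under 0.01, with a median of 38 to 40 beads per probe, a median standard error of 2.42 to 2.74% of the signal, and the 95th percentile of the signal at 7.74 to 10.7 times the median of undetected probes. The scripts were tested on simulated data with known changes in 11047 probes. Over all pairs a log2 change of 1 was recovered in 65% of changed probes for genotype, 53% for stimulation and 52% for population, and a change of 2 in 93%, 92% and 85%. Within CD25High cells a change of 2 was recovered in 47% for genotype and 44% for stimulation, and within CD45High cells in 62% and 48%. A change of 1 was recovered within either population in 1% of changed probes or fewer, so 0 calls within a population says little about changes of that size. The simulated noise of a probe had the same spread on all arrays. In the data the SD of the genotype difference was 0.815 in the stimulated CD25High pair and 0.233 to 0.299 in the others. The recovered shares need not hold there, and 0 calls over all pairs does not exclude such changes.

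The named genes were fixed by rule: per comparison the 8 probes with the largest rise and the 8 with the largest fall among calls with the same sign in every pair. Where fewer than 3 passed in a direction, the 8 largest values with the same sign in every pair, at least 1.5-fold apart and detected on every array of the higher group, are given as values. Up to 4 members per gene list and a set of genes written down beforehand (among them Foxp3, Il2ra, Ctla4, Ikzf2, Il10, Pdcd4, Vmp1, Fos and Egr1) were added. Il2, Spry1 and Mir21 have no probe under those symbols in the table used, and Nr4a1 has 1 probe that did not pass the filter. A gene with several probes is given by the probe the rule picked, and in gene lists by its brightest probe. Where a probe was detected on no array of the lower group, each of its values there was raised to at least the lowest detected value of that array, and the fold is given as "at least". Symbols in the file were matched to the gene table of assembly GRCm38.p6: 20733 as current symbols, 3871 as older ones and 1093 not matched, and Vmp1 is Tmem49 in the file.

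Gene lists, 17 in all, were written before the data were examined: Treg, naive and conventional, effector and memory, cytokine, immediate early and early activation, described miR-21 target, near Mir21, interferon-stimulated, cell cycle, heat shock and handling stress, ribosomal protein and sex-linked genes, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, erythroid cells and platelets, and stromal and endothelial cells. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. None of the 36 list calls held with an estimated correlation, and none of the 45 made without the knockout CD25High stimulated array. With an estimated correlation camera has only the residual degrees of freedom of the fit, so that test is weak. Its lowest adjusted p by camera in any comparison with all arrays was 0.106, between the populations. A miss in it does not exclude a list difference.

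Alternatives were no background correction, cyclic loess, the authors' values, no detection filter, detection on 4 arrays, a trended and robust eBayes, no block, an additive or full 2-way model, each pair left out, the mean over probes of a gene, and a 2-fold size rule. Leaving out the knockout CD25High stimulated array (for gene lists also with an estimated correlation), array weights, and the full 2-way model for comparisons over all pairs were added after the data were seen. A comparison of genes by miR-21 seed sites was not run, since no 3' UTR sequence was among the references. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.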

Results

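Messenger RNA was measured on 8 arrays, 1 for each combination of genotype (Mir-21 knockout or wild-type littermate), sorted CD4 T cell population (CD25High or CD45High) and stimulation state (none, or 30 min with antibodies against CD3 and CD28). CD25 is the alpha chain of the interleukin 2 receptor and is abundant on regulatory T cells. The CD45 isoform behind the CD45High sort is not given in the sources used here. No combination was repeated, so matched combinations served as pairs, and the number of arrays limits the precision of every difference. The p-values measure consistency across sorted populations and stimulation states, not across mice.

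The sort and the stimulation were visible in marker genes. Foxp3, the transcription factor that defines regulatory T cells, was 5.65 higher in CD25High than in CD45High cells (probe ILMN_2635132, log2, SE 0.12, 4 pairs). Crem, a repressor and activator of cyclic AMP responsive genes, was 3.40 higher after stimulation (log2, SE 0.25, 4 pairs). The knockout CD25High stimulated array stood apart: its median correlation with the other arrays was 0.888 against 0.938 to 0.965 for the rest, computed across genes, which are not independent replicates. It had 9208 probes detected against 9543 to 10477 on the other arrays, and 290 probes were more than 2-fold higher and 1121 more than 2-fold lower in knockout than wild type in its pair. Counts are therefore given below also without this array, a choice made after the data were seen.

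**Figure D1:**
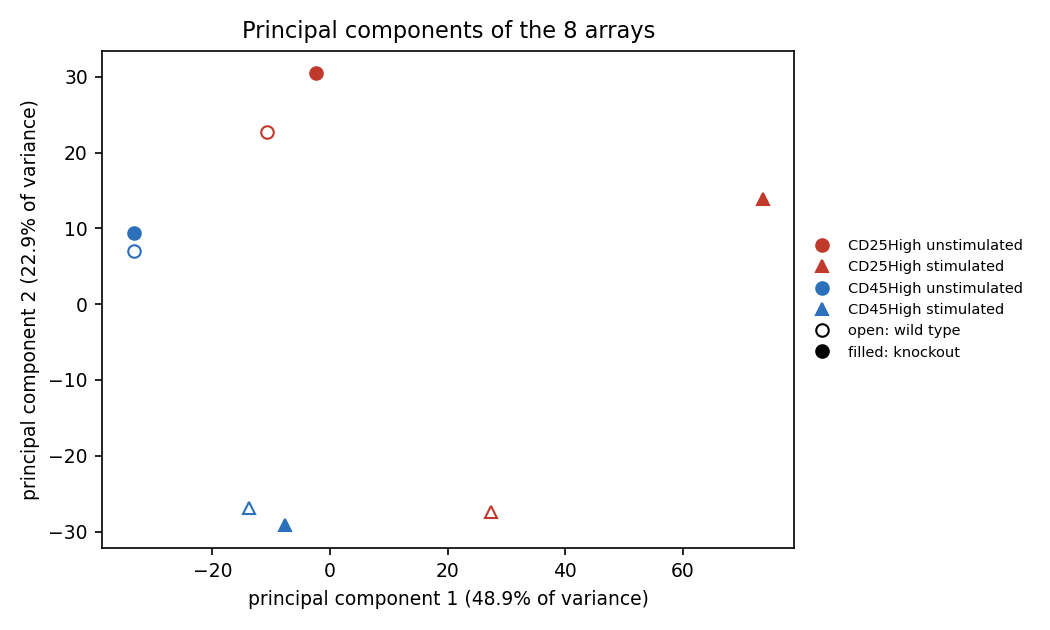
Each array on the first and second principal components of the tested probes, which hold 48.9% and 22.9% of the variance. The knockout CD25High stimulated array lies at 73.6 on the first component and the others between -33.3 and 27.4.

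Whether the labels of genotype hold was looked at first. Mir21 itself has no probe under that symbol in the table used, so the deletion was not measured directly. Vmp1, which encodes a membrane protein needed for autophagy and is the neighbour of Mir21 in the GRCm38.p6 gene order, separated the genotypes on all 8 arrays with probe ILMN_2861787. This probe was detected on 4 of 4 knockout and 0 of 4 wild-type arrays and was 1.88 ± 0.70 higher in knockout (log2, SD, 4 pairs), at least 3.08-fold. Whether it lies beside or inside the deleted segment is not given in the sources used here, so it checks the grouping of the arrays and not the deletion. The other Vmp1 probes differed in sign: ILMN_2591777 -0.98, ILMN_2591781 -0.94, ILMN_2616768 -0.93 and ILMN_2767635 0.51, and the first and second of these were detected on 0 knockout and 3 wild-type arrays, so their differences are at least 1.41-fold and at least 1.26-fold lower. With the knockout CD25High stimulated array left out, ILMN_2591781 had -0.59 and ILMN_2616768 -0.49.

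**Figure D2:**
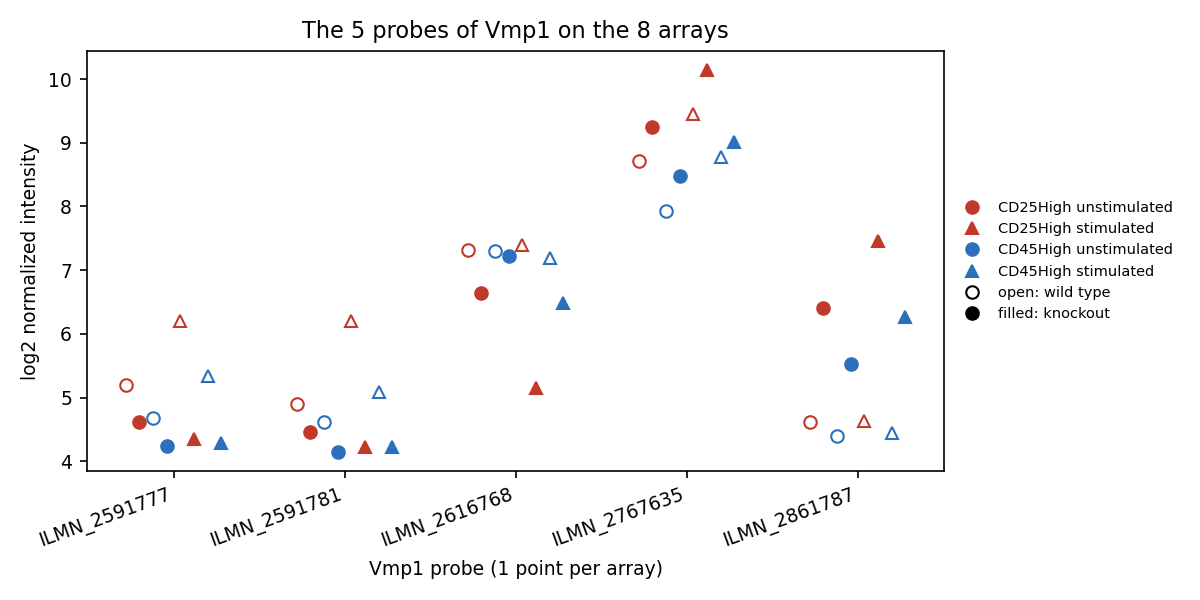
Log2 normalized intensity of the 5 Vmp1 probes on each of the 8 arrays. Knockout minus wild type, the mean over 4 pairs was 1.88 for ILMN_2861787 and -0.98 for ILMN_2591777.

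Across all 4 knockout and wild-type pairs, no gene passed the test, and the values that follow are not calls. After Vmp1, the genes with the largest mean difference above 0 and the same sign in every pair were Actb, cytoskeletal actin (ILMN_1377923, 1.27 ± 0.90, log2, SD, 4 pairs), Slc15a2, a peptide transporter (1.05 ± 0.55), and Haspin, a histone kinase of mitosis (0.88 ± 0.35). They were followed by Prf1, the pore-forming protein of cytotoxic granules (0.83 ± 0.49), and Ifngr2, a chain of the interferon gamma receptor (0.74 ± 0.30). Nle1 and Chka, a ribosome assembly factor and choline kinase, had values of 0.74 ± 0.25 and 0.70 ± 0.45. The Actb value is that of a single probe, and the Actb probes did not agree, as given for CD25High cells below. Below 0 in every pair were Hspa8, a constitutive chaperone (-2.33 ± 3.41, with -7.44 in the pair of the knockout CD25High stimulated array), Eif5a (-2.01), Eif4g2 (-1.78) and Eef2 (-1.62), factors of translation, Msn (-1.80) and Coro1a (-1.62), proteins of the actin cortex, Rbbp7 (-1.67), a histone binding protein, and Tagap (-1.59 ± 1.24), a GTPase activator of T cells. These values shrank in size when the knockout CD25High stimulated array was left out: Hspa8 -0.63, Eif5a -0.42, Eif4g2 -0.70, Eef2 -0.44, Msn -0.39, Coro1a -0.31, Rbbp7 -0.56 and Tagap -0.996. Among genes fixed in advance, the 3 Foxp3 probes had -0.21 (ILMN_2635132), -0.16 (ILMN_2917180) and -1.11 (ILMN_1225330), the last with -3.63 in the pair of that same array and a mean of -0.27 without it. Il10 was at -0.42 and Pdcd4, a described target of miR-21 and inhibitor of translation, at -0.14 (-0.05 without that array).

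With limma, 0 of 11047 probes passed at an adjusted p of 0.05 and 1083 had an unadjusted p under 0.05, against 552.35 expected by chance (lowest adjusted p = 0.493). The count stayed 0 under every other setting of background correction, normalization, filter and model, with 310 to 2038 probes at an unadjusted p under 0.05. When the knockout CD25High stimulated array was left out, 1 probe passed, Vmp1 ILMN_2861787 (log2 1.57, SE 0.15, adjusted p = 0.0462), and 1236 had an unadjusted p under 0.05. Read by size alone, 2 probes were at least 1.5-fold higher and 5 at least 1.5-fold lower in knockout in all 4 pairs, and 6 were that far apart in every pair but not in the same direction.

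Among the fixed gene lists, 0 members passed in the genotype comparison over all pairs, and list tests gave these results. Immediate early and early activation genes, which respond to receptor signals within minutes, had a median of -0.27 with 10 of 39 members above 0 (adjusted p = 9.03e-05, and adjusted p = 0.547 with an estimated correlation). Interferon-stimulated genes had a median of -0.03 with 13 of 29 above 0 (adjusted p = 0.0327, and adjusted p = 0.547 with an estimated correlation). Leaving out the knockout CD25High stimulated array, the interferon-stimulated median was -0.22 with 5 of 29 above 0 and 6 lower adjusted over the list alone (adjusted p = 5.35e-10, and adjusted p = 0.276 with an estimated correlation). The heat shock median was then -0.08 (adjusted p = 0.014, and adjusted p = 0.532 with an estimated correlation). With all arrays heat shock and handling stress genes had a median of -0.15 (adjusted p = 0.0292, and adjusted p = 0.428 with an estimated correlation), and all 5 sex-linked genes measured lay above 0 (adjusted p = 0.043, and adjusted p = 0.428 with an estimated correlation). Described miR-21 targets had a median of 0.04 with 17 of 32 members above 0 (adjusted p = 0.849), and genes near Mir21 a median of 0.05 (11 measured, adjusted p = 0.414), with 1 member higher and 1 lower adjusted over the list alone, Vmp1 (0.51) and Tubd1 (-0.47). Markers of other cells had medians of 0.13 for B cells (10 of 16 above 0, adjusted p = 0.414), 0.13 for CD8 T and NK cells (adjusted p = 0.414), 0.04 for myeloid and dendritic cells (adjusted p = 0.414) and -0.19 for stromal and endothelial cells (3 measured, adjusted p = 0.338). Several of these medians moved with the knockout CD25High stimulated array: without it they were -0.005 for miR-21 targets, -0.02 for genes near Mir21, 0.05 for CD8 T and NK cells and -0.06 for myeloid and dendritic cells (adjusted p = 0.218 or above), with 0.10 for B cells. With all arrays, median and test differed in sign for the miR-21 targets, genes near Mir21, effector and memory genes and myeloid markers, each with a median above 0 and a test pointing down, and the means of the genes near Mir21 (-0.02) and of the myeloid markers (-0.10) were below 0.

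In CD25High cells, the genotype difference was again a set of values and not of calls. Vmp1 ILMN_2861787 was 2.31 ± 0.73 higher in knockout (log2, SD, 2 pairs), at least 4.56-fold. Above 0 in both pairs were also St6galnac2 (1.88), a sialyltransferase, Prf1 (1.20), Dtx1 (1.11), a ubiquitin ligase of the Notch pathway, and Cst7 (1.08), a protease inhibitor. Actb had the largest of these other values, and its probes did not agree. A further Actb probe, given below for stimulation, fell further with stimulation in knockout than in wild-type CD25High cells. The probes with values above 0 differed in how far they rested on 1 array. ILMN_2588055 had a wide spread (2.30 ± 3.15, and 0.07 without the knockout CD25High stimulated array), while ILMN_1377923 had 1.97, and 1.49 without that array (adjusted p = 0.011 there). Cst7 had 0.69 without it. Below 0 were Hspa8 (-4.17 ± 4.62), Eif5a (-3.65), Ppp1ca (-3.60), a catalytic subunit of protein phosphatase, Msn (-3.38), Eif4g2 (-2.99), Eef2 (-2.98), Coro1a (-2.96) and Rbbp7 (-2.93). Their size rested on the knockout CD25High stimulated array, without which they had values from -0.96 (Eif4g2) to -0.34 (Ppp1ca). Immediate early and early activation genes had a median of -0.27 with 9 of 39 above 0 (adjusted p = 3.55e-05, and adjusted p = 0.789 with an estimated correlation). Leaving out the knockout CD25High stimulated array, their median was -0.53 with 4 of 39 above 0 and 14 lower adjusted over the list alone (adjusted p = 1.61e-16, and adjusted p = 0.802 with an estimated correlation). The interferon-stimulated median turned from 0.13 (adjusted p = 0.776) to -0.23 without that array (adjusted p = 2.38e-05, and adjusted p = 0.802 with an estimated correlation). Effector and memory genes had a median of 0.19 (adjusted p = 0.418), and of 0.14 without it (adjusted p = 0.0282, and adjusted p = 0.802 with an estimated correlation).

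For CD25High cells limma called 0 probes, with 1794 at an unadjusted p under 0.05 against 552.35 expected by chance (lowest adjusted p = 0.291). Every planned change of processing that kept all arrays also gave 0. The error was shared with the CD45High pairs, whose SDs were 0.233 and 0.299 against 0.815 in the stimulated CD25High pair. The number 1794 may thus be too high. With the knockout CD25High stimulated array left out, 18 probes passed, 6 higher and 12 lower in knockout, on the unstimulated pair alone, whose error was borrowed from the CD45High pairs. These 18, named after their values were seen, included Vmp1 (1.79), Actb (ILMN_1377923, 1.49), Prf1 (1.49) and Chka (1.35) above 0, and Rgs16 (-1.76), Areg (-1.59), Plk2 (-1.56), Klf4 (-1.51), Ifit3 (-1.46) and Usp18 (-1.34) below 0. Without the CD25High unstimulated pair 3099 probes passed, and only the pair of the array that stood apart was then left in this population. By size, 78 probes were at least 1.5-fold higher and 247 at least 1.5-fold lower in knockout in both pairs, with 22 that far apart in opposite directions, and 7 and 44 with no background correction.

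In CD45High cells Vmp1 ILMN_2861787 was 1.46 ± 0.49 higher in knockout (log2, SD, 2 pairs), at least 2.08-fold. The other largest values above 0 were Slc15a2 (1.05), Ms4a6b (0.89), a membrane protein of T cells, Slc25a27 (0.82), Rchy1 (0.79), a ubiquitin ligase, Haspin (0.75), Nle1 (0.70) and Nkain2 (0.68). Below 0 were Nup88 (-1.21 ± 0.48), a nuclear pore protein, Tagap (-0.88), Rgs1 (-0.82), a brake on G protein signals, Capn2 (-0.76), Rps6kb1 (-0.74), the S6 kinase beside Mir21, Mrps23 (-0.73), Cnot2 (-0.72) and Galnt10 (-0.71). Here 0 probes passed with limma, and 137 had an unadjusted p under 0.05 against 552.35 expected by chance (lowest adjusted p = 1). No other planned setting with all arrays gave a call. The error was shared with CD25High cells, where the SD of the genotype difference was 0.815 in the stimulated pair, against 0.233 and 0.299 here. The p-values here may thus be too large, and 0 calls says little about CD45High cells. Without the knockout CD25High stimulated array, or without the CD25High unstimulated pair, 3 probes passed: Vmp1 (1.46), Nup88 (-1.21) and 4933427D14Rik (-1.41). The last was named after its values were seen. Their differences are the same in those fits, and the error then came from the CD45High pairs alone, with 1 residual degree of freedom.

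Gene lists in CD45High cells had small differences between genotypes. Interferon-stimulated genes had a median of -0.21, with 3 of 29 above 0 (adjusted p = 7.03e-06, and adjusted p = 0.564 with an estimated correlation). B cell markers had a median of 0.15, with 16 of 16 above 0 (adjusted p = 0.00126, and adjusted p = 0.564 with an estimated correlation). Effector and memory genes had a median of -0.11 (adjusted p = 0.0174, and adjusted p = 0.564 with an estimated correlation). Treg genes and the heat shock list had adjusted p = 0.0288 each, and sex-linked genes adjusted p = 0.00633, all with adjusted p = 0.564 with an estimated correlation. With cyclic loess normalization the Treg result was adjusted p = 0.086. Immediate early genes had a median of -0.11 (adjusted p = 0.0887), a call without the knockout CD25High stimulated array (adjusted p = 0.0456, and adjusted p = 0.758 with an estimated correlation).

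The genotype difference was then compared between populations and between stimulation states. Between populations, immediate early genes had a median of -0.20, CD25High minus CD45High (adjusted p = 0.00739, and adjusted p = 0.931 with an estimated correlation), B cell markers -0.24 (adjusted p = 0.0135, and adjusted p = 0.931 with an estimated correlation) and effector and memory genes 0.32 (adjusted p = 0.0284, and adjusted p = 0.931 with an estimated correlation). The effector and memory result had adjusted p = 0.066 with the mean over probes of a gene. When the knockout CD25High stimulated array was left out, the immediate early median was -0.52 with 6 of 39 above 0 (adjusted p = 9.89e-12, and adjusted p = 0.965 with an estimated correlation). The Treg median was then 0.34 (adjusted p = 0.00187, and adjusted p = 0.965 with an estimated correlation), against 0.09 with all arrays (adjusted p = 0.928). For single probes 0 passed with limma, 397 had an unadjusted p under 0.05 (lowest adjusted p = 0.825), and without the knockout CD25High stimulated array the numbers were 0 and 423. Leaving out the CD25High unstimulated pair gave 1783. Only the pair of the array that stood apart was then left in CD25High cells, so that count is not read as a difference between populations. With all arrays 552.35 probes were expected at an unadjusted p under 0.05 by chance, more than the 397 seen, so these p-values may be too large. No single gene is thus shown to differ between the populations in its response to the deletion.

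Between stimulation states, early activation genes had the largest list difference of the genotype comparisons. Their knockout minus wild-type median was -0.53 in unstimulated CD25High cells (4 of 39 genes above 0) and -0.45 in unstimulated CD45High cells (3 of 39), but 0.08 (23 of 39) and 0.34 (31 of 39) in the stimulated ones. The difference of differences had a median of 0.66 with 34 of 39 above 0 (adjusted p = 1.66e-13, and adjusted p = 0.808 with an estimated correlation). Members with large values were Fosb, a subunit of AP-1 (2.34, SE 0.36), Tnfaip3, an inhibitor of NF-kappaB signals (2.05, SE 0.28), Gadd45b, a stress-induced activator of MAP kinase cascades (1.98, SE 0.46), and Ier3, an early response gene (1.58, SE 0.35). Fosb lay at -1.61 and -1.48 in the unstimulated pairs of CD25High and CD45High cells and at 0.32 and 1.26 in the stimulated ones, and Tnfaip3 at -1.68, -1.53, 0.17 and 0.73.

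For the same difference, limma called 0 single probes over all genes. An unadjusted p under 0.05 was seen for 403, against 552.35 expected by chance (lowest adjusted p = 0.863), so these p-values may be too large. Adjusted over the list alone, 10 early activation genes passed as higher. Without the knockout CD25High stimulated array 6 probes passed, 5 higher and 1 lower: Fosb (2.81), Gadd45b (2.55), Tnfaip3 (2.33), Irs2 (2.18), Ier3 (2.00) and S100a8 (-2.10). In that fit the stimulated arm is 1 pair, of CD45High cells, whose spread is taken from the unstimulated pairs. There 25 early activation genes passed adjusted over the list alone. The list median was then 0.82 (adjusted p = 1.61e-29, and adjusted p = 0.822 with an estimated correlation). Myeloid and dendritic markers had a median of -0.23 and a mean of -0.51, with 1 of 15 called lower and 4 adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.907 with an estimated correlation), against a median of -0.06 with all arrays (adjusted p = 0.181). Effector and memory genes had -0.22 (adjusted p = 0.0178, and adjusted p = 0.907 with an estimated correlation), against -0.08 (adjusted p = 0.162). Irs2 and S100a8 were named after their values were seen. Without the CD45High stimulated pair, only the pair of the knockout CD25High stimulated array was left in the stimulated arm. The probes passing in that fit are not read as a difference between stimulation states.

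**Figure D3:**
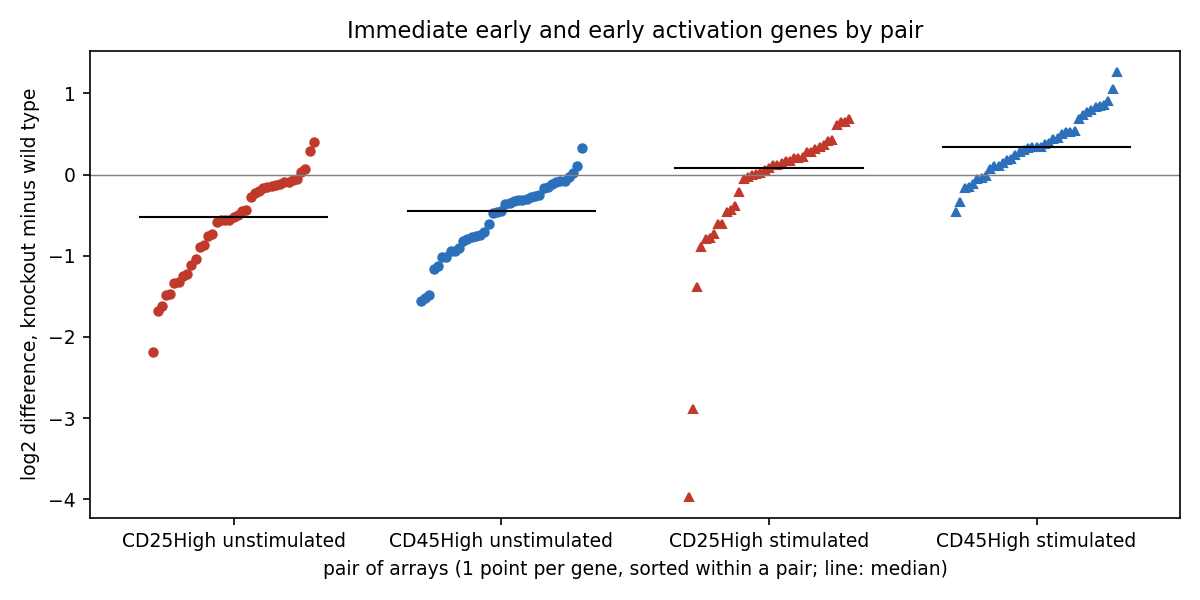
Knockout minus wild-type log2 difference of 39 immediate early and early activation genes in each pair. Medians were -0.53 and -0.45 in the unstimulated pairs of CD25High and CD45High cells and 0.08 and 0.34 in the stimulated pairs.

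Stimulation for 30 min was compared over all 4 pairs and in each population, and not tested within a genotype. The largest rises over all 4 pairs were in Crem (log2 3.40, SE 0.25, 4 pairs, adjusted p = 0.00478), Irf4, a transcription factor induced through the T cell receptor (3.15, SE 0.40), Ramp3, a partner of calcitonin family receptors (2.93, SE 0.72), Il4i1, a secreted amino acid oxidase (2.93, SE 0.25), Rel, a subunit of NF-kappaB (2.91, SE 0.34), Bhlhe40, a transcription factor of activated T cells (2.70, SE 0.22), Nr4a3, an orphan nuclear receptor (2.63, SE 0.25, at least 5.52-fold), and Cdkn1a, the cell cycle inhibitor p21 (2.47). The largest falls were in Dtx1 (-2.44, SE 0.23, adjusted p = 0.00621), Igfbp4 (-2.36), a binding protein of insulin-like growth factors, Usp18 (-2.26), a protease of the interferon response, Phf11 (-2.22), Lyz2 (-2.18, SE 0.56), the lysozyme of myeloid cells, Emp3 (-2.16), Ampd1 (-2.13), an AMP deaminase, and Sit1 (-2.09), an adaptor below the T cell receptor. Il2ra rose by 1.44 (SE 0.18) and Pdcd4 fell by 1.56 (SE 0.15). Fos and Egr1, classical early genes, did not pass (-0.60, adjusted p = 0.123, and -0.05, adjusted p = 0.847). Ctla4 had 1.09 (adjusted p = 0.0965), Il10 0.48 and Ikzf2 -0.47, the last pair of genes at 0.29 and -0.02 without the knockout CD25High stimulated array. The 3 Foxp3 probes disagreed, with 0.74 passing (ILMN_2917180, adjusted p = 0.0219) and 0.46 and -0.87 not passing, the last at -0.04 without that array.

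Limma called 1771 of 11047 probes with stimulation, 876 higher (766 genes) and 895 lower (757 genes), and 232 and 263 of them moved more than 2-fold. Without the knockout CD25High stimulated array, and with it its pair, the count was 2516, 1189 higher and 1327 lower. The count was 0 without the CD25High wild-type pair (2513 at an unadjusted p under 0.05), 739 without the CD45High wild-type pair and 111 without the CD45High knockout pair, and of the 20 probes named here as calls 0, 16 and 9 still passed. It was 1163 with no detection filter and 1026 with no replicate block.

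**Figure D4:**
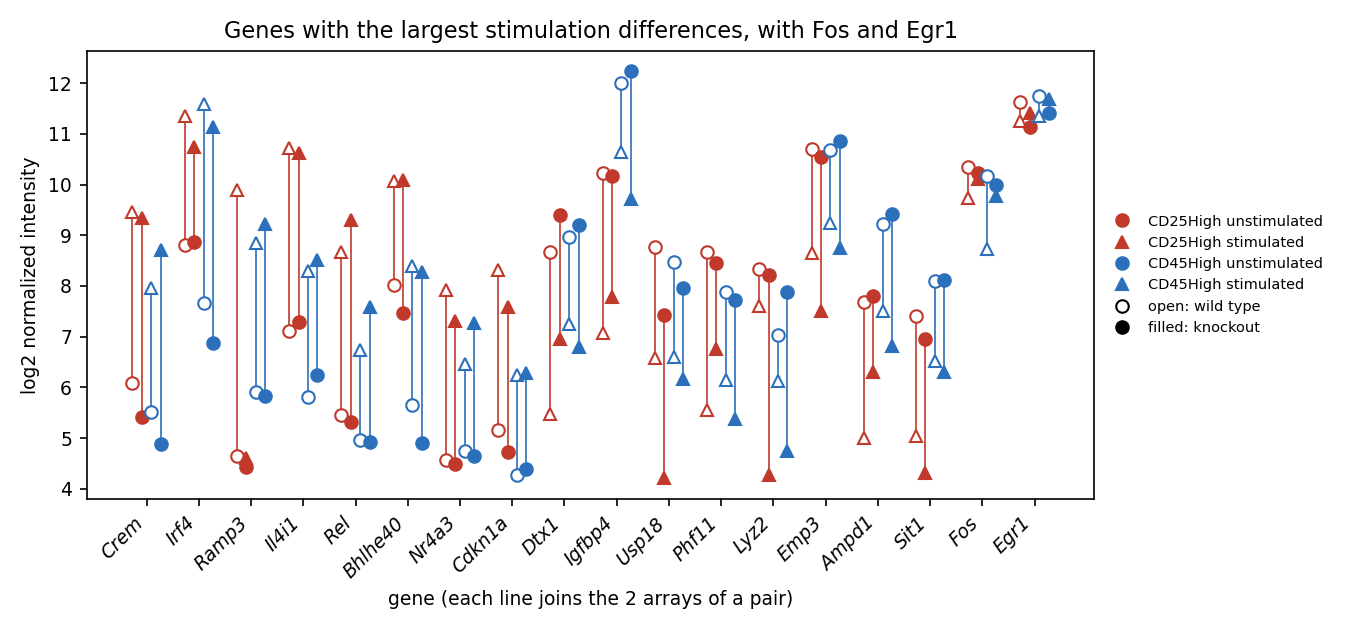
Log2 normalized intensity on each array of the named genes with the largest stimulation differences, with Fos and Egr1, each line joining the arrays of a pair. Crem had the largest mean rise (3.40) and Dtx1 the largest mean fall (-2.44).

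Among gene groups over all pairs, interferon-stimulated genes had the most members that fell: 14 of 29, with 1 higher, and 20 and 2 adjusted over the list alone (median -0.72, adjusted p = 1.98e-06, and adjusted p = 0.795 with an estimated correlation). Examples were Oas2 (-1.94), Ifit3 (-1.70) and Rsad2 (-1.66), effectors against viruses, while Gbp3 rose (0.62). Of 14 cytokine genes 4 rose and 0 fell (adjusted p = 0.018, and adjusted p = 0.795 with an estimated correlation): Tnf (1.46), Il3 (1.45), Xcl1 (1.35) and Tnfsf11 (0.84). Of 39 early activation genes 12 rose and 3 fell, 14 and 5 adjusted over the list alone (adjusted p = 0.14), the falls being in Jund (-1.29), Ier2 (-0.88) and Id3 (-0.57). When the knockout CD25High stimulated array was left out, these numbers were 2 higher and 20 lower for interferon-stimulated, 5 and 1 for cytokine, and 15 and 8 for early activation genes.

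Of 28 Treg genes 10 rose, led by Cd83 (2.35), Swap70 (2.15) and Tnfrsf4 (1.98), and 4 fell, among them Izumo1r (-1.57) and Gpr83 (-1.05), with 12 and 6 adjusted over the list alone (adjusted p = 0.14). Naive and conventional T cell genes were split, with 3 of 17 higher, such as the homing receptor Ccr7 (1.72), and 3 lower, such as Art2b (-1.92), 3 and 4 adjusted over the list alone (adjusted p = 0.638). Effector and memory genes had 4 higher and 5 lower of 28, 5 and 5 adjusted over the list alone (Ccl4 2.42, Vim -1.31; adjusted p = 0.638, with a median of -0.08 and a mean of 0.02). Of 32 described miR-21 targets 4 rose, Map2k3 (1.70), Satb1 (0.89), Apaf1 (0.82) and Skp2 (0.48), and 4 fell, Pdcd4 (-1.56), Tnfaip8l2 (-0.92), Glcci1 (-0.56) and Pik3r1 (-0.55), with 4 and 5 adjusted over the list alone (adjusted p = 0.881). Of 15 myeloid and dendritic markers 0 rose and 6 fell, 2 and 8 adjusted over the list alone (adjusted p = 0.14). Of 8 CD8 T and NK markers 1 rose and 3 fell, 2 and 4 adjusted over the list alone (adjusted p = 0.291). Leaving out the knockout CD25High stimulated array gave Treg counts of 13 higher and 4 lower, and the Treg median went from 0.18 to 0.29 (adjusted p = 0.00904, and adjusted p = 0.771 with an estimated correlation). Myeloid counts were then 1 and 6, with a median of -0.41 against -0.45 (adjusted p = 0.046, and adjusted p = 0.771 with an estimated correlation), and the miR-21 target median went from 0.08 to 0.01.

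In CD25High cells the largest rises with stimulation were in Crem (3.65, SE 0.29, 2 pairs, adjusted p = 0.00603), Rel (3.60), Il4i1 (3.48), Nr4a3 (3.09, at least 7.59-fold), Csf2, the cytokine GM-CSF (3.08, at least 6.45-fold), Pdgfa, a growth factor (3.06), Marcksl1 (3.04) and Ccl4, a chemokine (3.03). The largest falls were in Coro1a (-4.56, adjusted p = 0.0473, with -7.17 in the knockout pair), Actb (ILMN_2617433, -4.09, adjusted p = 0.0391), Ptprcap (-3.15), Igfbp4 (-3.07), Itgae (-2.86), the integrin CD103, Sigirr (-2.85), Dtx1 (-2.81) and Il6ra (-2.77), the interleukin 6 receptor. Calls with smaller falls when the knockout CD25High stimulated array was left out were Coro1a (-1.96), Actb (-1.99), Ptprcap (-2.01) and Sigirr (-1.86). The Actb fall is that of a single probe, and another Actb probe was higher in knockout than wild type on that array, as given above. Of 14 cytokine genes 7 rose and 0 fell, 9 and 1 adjusted over the list alone (adjusted p = 8.36e-05, and adjusted p = 0.651 with an estimated correlation), and of 29 interferon-stimulated genes 0 rose and 7 fell, 1 and 13 adjusted over the list alone (adjusted p = 8.36e-05, and adjusted p = 0.802 with an estimated correlation). Early activation genes had 10 higher and 1 lower of 39, 14 and 3 adjusted over the list alone (adjusted p = 0.0415, and adjusted p = 0.873 with an estimated correlation). B cell markers had 6 higher and 0 lower of 16 (Fcer2a 2.27, adjusted p = 0.0306, and adjusted p = 0.826 with an estimated correlation). The early activation and B cell lists had adjusted p = 0.0578 (median 0.16 against 0.37) and adjusted p = 0.0776 (median 0.31 against 0.47) without the knockout CD25High stimulated array. In that fit 18 interferon-stimulated genes fell.

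The CD25High count was 1580 with limma, 823 higher (719 genes) and 757 lower (637 genes). It was 2527 without the knockout CD25High stimulated array, 1195 higher and 1332 lower, and without the CD25High wild-type pair 3997. Without either CD45High pair, from which part of the error estimate comes, it was 160, and 8 of the 21 probes named as calls no longer passed: those of Actb, Coro1a, Foxp3, Il10, Il2ra, Ptprcap, Sigirr and Vmp1. The count was 906 with no detection filter and 608 with array weights, the weights being chosen after the data were seen.

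In CD45High cells the largest rises were in Irf4 (4.08, SE 0.23, 2 pairs, adjusted p = 0.0257), Crem (3.15), Bhlhe40 (3.07), Zfp52 (2.89), Lad1 (2.63, at least 4.43-fold), Tnfrsf4, the costimulatory receptor OX40 (2.62), Tgif1 (2.51), a transcription repressor, and Cd83 (2.41), a surface protein of activated lymphocytes. The largest falls were in Ddit4, an inhibitor of mTORC1 (-2.12, adjusted p = 0.0266), Dtx1 (-2.06), Hspa1a, an inducible chaperone (-1.84), Sgk1, a kinase (-1.79), Fcgrt (-1.71), Sit1 (-1.69), E2f2 (-1.67) and Ckb (-1.63). Of 28 Treg genes 6 rose and 1 fell, 12 and 2 adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.526 with an estimated correlation). Interferon-stimulated genes had 0 called, but 1 higher and 16 lower adjusted over the list alone, and a median of -0.78 (adjusted p = 1.88e-06, and adjusted p = 0.526 with an estimated correlation). Of 15 myeloid markers 0 were called and 4 were lower adjusted over the list alone (adjusted p = 0.00736, and adjusted p = 0.526 with an estimated correlation). Calls without the knockout CD25High stimulated array were 12 higher and 4 lower for Treg, 1 and 19 for interferon-stimulated and 1 and 7 for myeloid genes. The CD45High differences are the same in that fit, and only the error estimate changed.

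The CD45High count was 109 with limma, 80 higher (70 genes) and 29 lower (28 genes). It was 2467 without the knockout CD25High stimulated array, 0 without either CD45High pair (816 and 544 at an unadjusted p under 0.05, 0 of 18 named probes passing), 0 with no detection filter, 11 with cyclic loess, 72 with detection on 4 arrays, 321 with no background correction, 514 with a trended and robust fit and 1379 with array weights. The fit behind 2467 leaves the CD45High differences unchanged. Its error came from the CD45High pairs alone, with 1 residual degree of freedom, so the gain lies in the error estimate. With all arrays the error is shared by the populations, so 109 is no measure of the size of the CD45High response. Of the 109 probes 95 were also called in CD25High cells, all with the same sign. Of the 1580 called in CD25High cells 1467 had the same sign in CD45High cells. The correlation of the stimulation differences of the populations was 0.627 across probes, which are not independent replicates.

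The response to stimulation was set against itself between populations. Helper T cell cytokine genes had higher values in CD25High cells, with a median difference of 0.85 and 6 members passing adjusted over the list alone, among them Csf2 (3.10), Areg (2.53), Il5 (1.36) and Xcl1 (1.35) (adjusted p = 0.000103, and adjusted p = 0.375 with an estimated correlation). Effector and memory genes had a median of 0.54 (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00035, and adjusted p = 0.375 with an estimated correlation), and B cell markers 0.48 (3 higher adjusted over the list alone, adjusted p = 0.00404, and adjusted p = 0.511 with an estimated correlation). The B cell median was 0.29 without the knockout CD25High stimulated array (adjusted p = 0.0114, and adjusted p = 0.778 with an estimated correlation). Treg genes had a median of -0.48 (1 lower adjusted over the list alone, adjusted p = 0.00227, and adjusted p = 0.479 with an estimated correlation), and a median of -0.09 with adjusted p = 0.113 without the knockout CD25High stimulated array. Limma called 0 single probes over all genes, 1048 had an unadjusted p under 0.05 (lowest adjusted p = 0.294), and every planned setting with all arrays gave 0. Interferon-stimulated genes had a median of 0.05 (adjusted p = 0.662), and -0.22 without that array (adjusted p = 0.00236, and adjusted p = 0.726 with an estimated correlation). Called in that fit and not with all arrays were also heat shock genes (0.28, against 0.21 with adjusted p = 0.0716; adjusted p = 0.0056, and adjusted p = 0.726 with an estimated correlation) and myeloid markers (0.39, against 0.34 with adjusted p = 0.0716; adjusted p = 0.0324, and adjusted p = 0.778 with an estimated correlation). The same holds for CD8 T and NK markers (0.14, against 0.11 with adjusted p = 0.0683; adjusted p = 0.0302, and adjusted p = 0.743 with an estimated correlation). Without the knockout CD25High stimulated array 208 passed, 115 higher and 93 lower, with Pdgfa (3.52), Csf2 (3.43), Mt1 (3.31) and Hspa1a (2.59) above 0 and Ephx1 (-2.29), Cldn10 (-2.25) and Itgae (-2.20) below 0, picked by size after their values were seen. Without the CD25High wild-type pair, only the pair of the knockout CD25High stimulated array was left in that population. The probes passing in that fit are not read as a difference between populations.

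CD25High and CD45High cells differed by the genes of regulatory T cells. Higher in CD25High cells were Foxp3 (ILMN_2635132, log2 5.65, SE 0.12, 4 pairs, 50.3-fold, adjusted p = 2.8e-05, with 5.59 and 3.93 for its other probes), Socs2, a suppressor of cytokine signals (5.16, SE 0.17), Itgae (4.47, SE 0.35), Il10, an inhibitory cytokine (4.01, SE 0.21, at least 11.9-fold), Nrp1, a semaphorin receptor (3.97), Il2ra, the sort marker itself (3.78, SE 0.17, adjusted p = 0.000232), Rgs1 (3.69) and Axl, a receptor kinase (3.31). Ikzf2 (3.10), the transcription factor Helios, and Ctla4 (2.84), an inhibitory receptor, were also higher. Lower in CD25High cells were Pdlim4 (-3.36, SE 0.26), Igfbp4 (-2.69), Als2cl (-2.15), Lypd6b (-2.08), Pxylp1 (-2.05), Sema4a (-1.98), Lef1, a transcription factor of naive T cells (-1.98, adjusted p = 0.0426), and Nacc2 (-1.90). Vmp1 was higher on 1 of its probes (ILMN_2767635, 0.84, adjusted p = 0.0156). Its probe ILMN_2616768 was lower in CD25High than CD45High cells in both knockout pairs and a little higher in both wild-type pairs. Pdcd4 (-0.56, adjusted p = 0.0763), Fos (0.44) and Egr1 (-0.20) did not pass.

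Of 28 Treg genes 25 were higher in CD25High cells and 0 lower, 26 adjusted over the list alone (adjusted p = 1.05e-27, and adjusted p = 0.106 with an estimated correlation). Of 17 naive and conventional T cell genes 8 were lower, among them Il7r (-1.17), and 1, the survival gene Bcl2 (0.86), was higher, 10 and 1 adjusted over the list alone (adjusted p = 6.57e-05, and adjusted p = 0.106 with an estimated correlation). Effector and memory genes had 13 of 28 higher and 0 lower, 19 and 2 adjusted over the list alone (adjusted p = 1.44e-08, and adjusted p = 0.333 with an estimated correlation), such as the chemokine receptor Ccr6 (3.16), Ahnak (2.20) and S100a6 (1.91). Cell cycle genes had 12 of 28 higher and 0 lower, 19 adjusted over the list alone (adjusted p = 5.41e-09, and adjusted p = 0.106 with an estimated correlation), such as Tk1 (1.71), Birc5 (1.43) and Top2a (1.26). Early activation genes had 7 of 39 higher, 14 adjusted over the list alone (adjusted p = 2.29e-06, and adjusted p = 0.333 with an estimated correlation), such as Dusp4 (3.14), Rgs1 (3.05 on its brightest probe) and Bhlhe40 (2.11), and cytokine genes 4 of 14 (Areg 2.45, Lta 1.53; adjusted p = 0.00974, and adjusted p = 0.502 with an estimated correlation).

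Markers of other cells moved with the same comparison. Of 16 B cell markers 11 were higher in CD25High cells and 0 lower, 14 adjusted over the list alone (adjusted p = 6.73e-11, and adjusted p = 0.293 with an estimated correlation), with Cd79b, a chain of the B cell receptor (2.06), and Cd74 (1.85) and H2-Ab1 (1.69), of antigen presentation. Of 15 myeloid and dendritic markers 4 were higher, 7 adjusted over the list alone, among them Fcer1g (2.45) and Plac8 (1.88) (adjusted p = 0.000183, and adjusted p = 0.333 with an estimated correlation). Of 8 CD8 T and NK markers 3 were higher, 3 with 1 lower adjusted over the list alone (adjusted p = 0.117). Described miR-21 targets were split, with Tiam1 (2.40) and Bcl2 higher and Tgfbr2 (-0.68) and Yod1 (-0.58) lower of 32, 6 and 8 adjusted over the list alone (adjusted p = 0.947, with a median of -0.01 and a mean of 0.08). Interferon-stimulated genes had 1 higher, Gbp3 (2.48), and 2 lower, among them Oas2 (-1.43), 2 and 4 adjusted over the list alone.

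Limma called 917 probes between the populations, 598 higher (514 genes) and 319 lower (266 genes), with 339 and 101 more than 2-fold apart. Leaving out the knockout CD25High stimulated array gave 1343, 753 higher and 590 lower, with 28 of 28 Treg genes, 10 naive genes lower and 11 early activation genes higher. Without the wild-type unstimulated pair it was 320, without the knockout unstimulated pair 231 and without the wild-type stimulated pair 287, and 3 or 4 of the 21 named probes then no longer passed, among them those of Lef1 and Vmp1 and Foxp3 ILMN_1225330 each time. It was 559 with no detection filter, 493 with no replicate block, 1472 with the full 2-way model and 1926 with array weights.

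**Figure D5:**
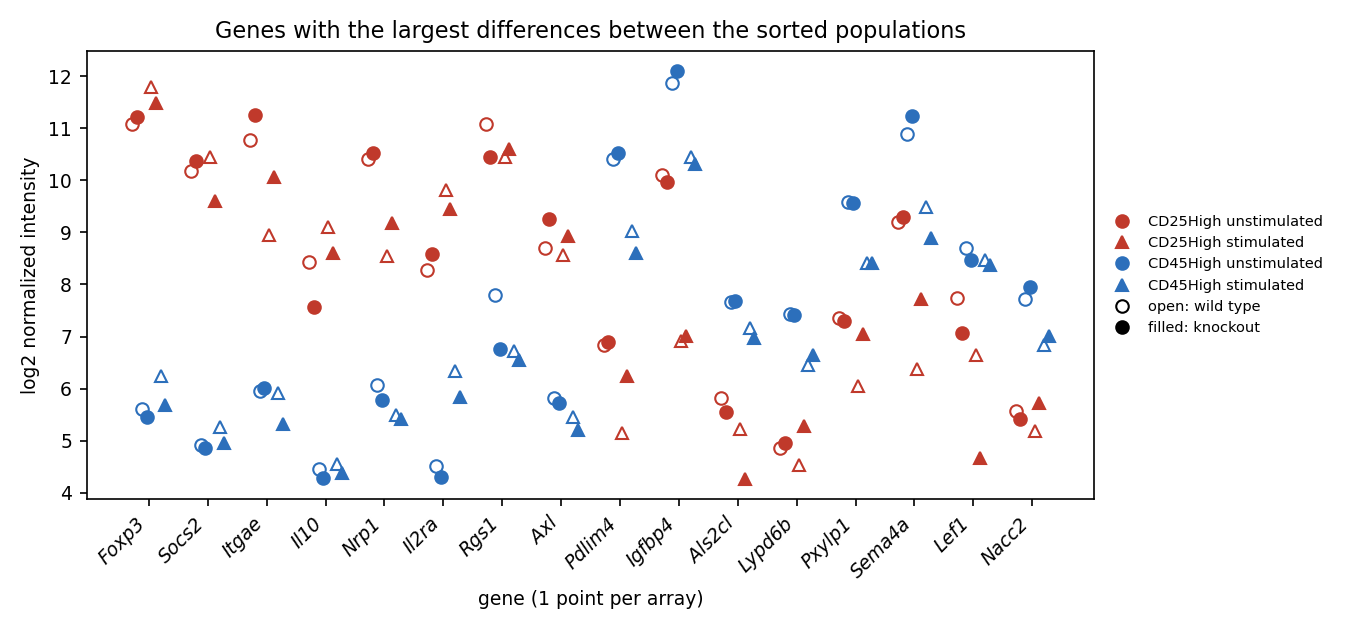
Log2 normalized intensity on each of the 8 arrays of the named genes with the largest differences between the populations. CD25High minus CD45High, the mean difference was highest for Foxp3 (5.65) and lowest for Pdlim4 (-3.36).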

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

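Leaving out the knockout CD25High stimulated array, with either correlation between genes, array weights and the full 2-way model over all pairs were chosen after the result was seen. With the authors' values every count of calls stayed within 1.5 times. Those values are nearly the same as the ones used here, so this is little check of the processing. Stimulation in CD45High cells still went from 109 to 81 calls. With no detection filter calls went from 1771 to 1163 (stimulation), 1580 to 906 (stimulation, CD25High), 109 to 0 (stimulation, CD45High) and 917 to 559 (population), with more probes tested. For stimulation in CD45High cells the count was 321 with no background correction (73% to 48% higher), 11 with cyclic loess, 72 with detection on 4 arrays and 514 with a trended and robust fit, and the cause was not tested. With no replicate block, stimulation gave 1026 and population 493, and genotype stayed at 0 calls (310 at an unadjusted p under 0.05, limma). Comparisons within populations and differences were not run without it. Without the knockout CD25High stimulated array the genotype counts were 1 (all pairs), 18 (CD25High), 3 (CD45High) and 6 (difference between stimulation states), and the stimulation counts 2527 (CD25High), 2467 (CD45High) and 208 (difference between populations). The differences within CD45High cells were the same in those fits, and only the error estimate changed. Array weights gave 608, 1379 and 1926 for stimulation in CD25High, in CD45High and population, and the full 2-way model 1472 for population.

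With each pair left out in turn the counts ranged from 0 to 1 (genotype, all pairs), 0 to 3099 (CD25High), 0 to 3 (CD45High), 0 to 1783 and 0 to 2098 (genotype difference between populations and stimulation states), 0 to 2516 (stimulation), 160 to 3997 (CD25High), 0 to 2467 (CD45High), 0 to 2029 (difference) and 231 to 1343 (population). A lone pair left in a population or stimulation state was assumed to vary like the other one. The highest counts in CD25High cells and for the differences came where that pair held the knockout CD25High stimulated array. No call of a named gene reversed. Of 18 named calls of stimulation in CD45High cells, 16 were lost with cyclic loess and 18 with no filter. Called over all pairs or in CD25High cells but not with a trended and robust fit were Ramp3 (adjusted p = 0.0997), Lyz2 (0.098), Lef1 (0.0738), Ptprcap (0.0791), Coro1a (0.233) and Actb (0.207), by limma. With the mean over probes, the sex-linked list (genotype, adjusted p = 0.0535) and the B cell list (stimulation in CD25High, adjusted p = 0.105) no longer passed. With background at this level, the size rule in CD25High cells gave 4 higher and 29 lower at 2-fold, and in CD45High cells 8 and 10 at 1.5-fold, with 25 in opposite directions, and 1 and 1 at 2-fold.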

Other observations

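The tests on flanking DNA, on the 100 genes nearest to Mir21, on a mislabelled sample and on Fos and Egr1 in this part were chosen after the result was seen. Genes of other groups also moved with stimulation over all 4 pairs. The Y-linked genes Ddx3y, an RNA helicase (log2 1.57, SE 0.21), and Eif2s3y, a translation factor (0.79, SE 0.16), rose, 2 of 5 sex-linked genes, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.14). Both Y-linked genes and Xist, the X-inactivation transcript, were measured in both genotypes. The sex of the mice was not part of the groups used here. A different mix of sexes between stimulated and unstimulated arrays was not tested and cannot be told apart from a response of these genes. Of 16 B cell markers 2 rose, among them Fcer2a (1.82), and Fcmr fell (-1.03) (adjusted p = 0.14). Of 15 heat shock and handling stress genes the mitochondrial chaperone Hspd1 rose (0.74) and Ddit4 fell (-2.02), with a median of 0.12, a mean of -0.13 and a test pointing up (adjusted p = 0.882). Of 28 cell cycle genes E2f2 (-1.57) and Tk1 (-0.86) fell, 1 adjusted over the list alone, with a median of 0.05, a mean of -0.05 and a test pointing down (adjusted p = 0.903). Of 11 genes near Mir21 Vmp1 (0.75 on its brightest probe) and Appbp2 rose (adjusted p = 0.638). The Vmp1 probe ILMN_2616768 fell in both knockout pairs and moved little in the wild-type ones. Of 54 ribosomal protein genes 1 rose and 2 fell (adjusted p = 0.185), and of 3 stromal and endothelial markers 0 passed (adjusted p = 0.461). The medians of heat shock and cell cycle genes were 0.01 and -0.01 without the knockout CD25High stimulated array.

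Between populations, the stromal marker Igfbp7 was higher in CD25High cells (0.84), 1 of 3, with a median of -0.09 (-0.21 without the knockout CD25High stimulated array) and a test pointing up (adjusted p = 0.927). Heat shock genes had 0 of 15 called (adjusted p = 0.334) and sex-linked genes 0 of 5 (adjusted p = 0.568). Of the erythroid and platelet list 2 genes were measured, with Hba-a1 at 0.51 and Car2 at -0.22 for genotype and 0.49 and 0.14 for stimulation, too few for a list test. In the genotype comparison over all pairs, cell cycle genes had a median of 0.14 with 22 of 28 above 0 (adjusted p = 0.171), naive genes 0.14 (adjusted p = 0.414), Treg genes -0.08 with 11 of 28 above 0 (adjusted p = 0.0731), cytokine genes -0.08 (adjusted p = 0.151) and ribosomal protein genes adjusted p = 0.0731. These medians were, without the knockout CD25High stimulated array, 0.05 for cell cycle genes (18 of 28 above 0), 0.03 for naive genes, -0.02 for Treg genes and -0.03 for cytokine genes (adjusted p = 0.396 each), and ribosomal protein genes had adjusted p = 0.148.

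Of the 100 genes with the lowest genotype p over all pairs, 16 lay on chromosome 11 of GRCm38.p6, the chromosome of Mir21, against 8.54 expected (Fisher's exact p = 0.0102, genes not being independent), and 8 of the 16 were higher and 8 lower. Without the knockout CD25High stimulated array 21 lay there, and within populations 21 in CD45High cells but 12 in CD25High cells (Fisher's exact p = 0.144), with 9, 13, 11 and 15 for the size of the difference in the unstimulated CD25High, unstimulated CD45High, stimulated CD25High and stimulated CD45High pair. A candidate explanation is DNA of the strain in which the deletion was made, still flanking the locus: 7 of the 16, Vmp1 among them, were within the 100 tested genes nearest to Mir21, against 2.42 expected (Fisher's exact p = 0.00526), while the share of genes at an unadjusted p under 0.05 among the nearest 200 against the rest gave p = 0.191 (9.5% and 7.16%), which excludes nothing. A property of the chromosome in any comparison also stays open, with 13 of 100 for stimulation and 5 for population (lower Fisher's exact p = 0.0826), since the bound set beforehand took a p above the threshold for absence. Flanking DNA thus stays open as well, since no sequence variants were used here and an effect of the deletion on its neighbours would look alike, and among 7 other swaps of genotype within pairs the highest number was 13.

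The knockout CD25High stimulated array may differ by uneven transcript coverage, from RNA quality or labelling. In its pair, the correlation between 2 probes of a gene was 0.283 across 2103 genes (bootstrap 95% interval over genes 0.225 to 0.346) although differences were large (SD 0.815), against 0.843 for the stimulation difference of wild-type CD25High cells (SD 0.644). Marker lists of other cell types had a highest median of 0.187, knockout minus wild type in this pair. B cell and myeloid markers were called higher in CD25High cells, so the CD4 sort by itself excludes no RNA of other cells. A stronger response to stimulation would give a positive correlation with the wild-type CD45High response, where -0.204 was seen. That test covers a stronger response only. A mislabelled sample is set against by the 20 probes that best separate each factor on the other 7 arrays, of which 17 lay on the labelled side for genotype, 19 for population and 18 for stimulation. Of the causes looked at, coverage is the candidate left, but a weaker response to stimulation was not tested. On the second principal component this array lay at 13.9 and the other stimulated arrays at -29.2 to -26.9. The other genotype pairs also had correlations of 0.235 to 0.307 between probes, at a smaller spread (SD 0.233 to 0.299). No RNA quality record was used here.

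Fos and Egr1 did not pass for stimulation while Irf4, Rel, Crem and Nr4a3 rose. Whether sorting and handling had already raised Fos and Egr1 stays open: both lay at or above percentile 91.7 of tested probes on unstimulated arrays, but signals of different probes depend on the probes and decide nothing here, and no array of unsorted cells was used. A saturated signal is unlikely, as their highest unstimulated signal was 15.6% of the brightest probe.

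Splits of the 8 arrays into 4 and 4, which ignore the pairs, were compared with the real ones. For stimulation 1 of 35 splits reached the real count (1026 calls, highest other 493, the population split), the smallest share this test can give. It does not exclude chance differences between animals or in handling, since no combination was repeated. The paired count of 1771 was 0 without the CD25High wild-type pair. For population 2 of 35 splits reached the real count of 493, the other being the stimulation split (1026), a structure of the samples, so the test decides nothing. The 32 splits that follow no factor gave at most 0 calls. Such splits leave the stimulation and population differences in the error, which favours 0 calls. They are thus no measure of chance, and 1 of 35 for stimulation decides nothing either. For genotype the real count is 0 (limma, 310 at an unadjusted p under 0.05), which 35 of 35 splits reach by construction (highest other 1026), so nothing is tested. Swaps within pairs are too few, 8, for a share under 0.05, and a turned pair moves a strong difference into the error, which favours 0 calls. Swaps reaching the real count numbered 8 for genotype (0 calls, highest other 0), 1 for stimulation (1771, highest other 0) and 1 for population (917, highest other 0).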
